A study of Mus musculus with 12 samples.

How the data were processed

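Total RNA of mouse corpus callosum was taken with a Qiagen RNeasy kit and turned into libraries with a SMARTER mRNA-Seq kit, per the labels' protocols. The series design names wild-type mice and mice lacking AHR in microglia in the cuprizone model, and the labels give each sample a genotype (WT or AHR CKO), a treatment (control or cuprizone) and a replicate number, which placed the 12 samples in 4 groups of 3. The dose and length of the cuprizone diet, the Cre line, the sex and age of the mice, and whether the replicates were separate animals are not given in the sources used here.

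The authors deposited 1 table of FPKM values with a gene symbol and 12 sample columns, per the file headers. The reads were placed on the mouse genome GRCm38 (mm10), per the submitters' processing notes. The aligner, the quantifier and its version, the annotation and any filter applied before deposit are not given in the sources used here. FPKM divides fragments by transcript length and library size, so it removes the first-order effect of length but not a length trend that differs between libraries, and it lets a few very abundant genes shift all others. The table held 15584 genes, 15275 of them above 0 in every library. In 5 of the 6 WT libraries no gene was listed at 0, whereas WT cuprizone replicate 2 had 94 and the AHR CKO libraries had 52 to 80, and an exact 0 is therefore given only as listed. In 25 symbols a spreadsheet had turned the name into a date. They stayed in the tests but are not named, and no result is drawn from them.

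Totals per library ran from 447156 to 519470 and median values from 8.24 to 9.11 FPKM. Since FPKM hides the read number, depth was estimated from the steps in FPKM times length among 3116 genes with 1 RefSeq transcript and a length over 1500 nt, taking 1 step as 1 fragment. The step was the median of the values between 0.05 and 0.12 FPKM times kb (11 to 36 genes per library), a range set after looking at the values that limits the answer to between 8330000 and 20000000 fragments. This gave 11300000 to 14700000 fragments per library. Of the values up to 2.5 steps, 58.06% to 76.47% lay within 0.2 of a whole multiple, against 40% by chance. Counts were not recovered and no count test was run.

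Genes with FPKM of at least 1 in at least 3 of the 12 libraries were tested, which left 13759 (88.29%). Values were transformed as log2(FPKM + 1), so log2 changes understate those of low genes. A model with the 4 groups as terms was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend), so that all groups shared 1 estimate of the spread. The comparisons were cuprizone against control in each genotype, AHR CKO against WT in each treatment, the genotype by treatment interaction, and AHR CKO against WT averaged over both treatments. P-values are two-sided, were adjusted by the Benjamini-Hochberg method within each comparison, and passed under 0.05. Means ± SD are of the FPKM values themselves, and folds are ratios of those means.

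In total 37 gene lists of cell types and pathways were written before the data were examined, as were the design, the alternatives and the rule for naming genes. They held 622 symbols, of which 563 were in the table, 5 of them under an older name, and 533 were tested. Each list with at least 3 tested members was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Members were also counted past the threshold over all genes and adjusted over the list alone.

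The text names genes by this rule. Ahr, Cx3cr1, Cyp1b1, Tiparp, Ahrr and Nqo1 were always followed. Each comparison adds the 10 largest increases and the 10 largest decreases among named, non-predicted genes past the threshold whose groups did not overlap (for the interaction without this last condition). Each list adds up to 4 members with the smallest adjusted p, or up to 2 of the highest FPKM where none passed, and a comparison with fewer than 10 calls adds the 10 genes of smallest p. Results for some single genes under this rule are not reported here, and they are left out of the counts of named calls.

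The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling to a common total (TPM), median-of-ratios scaling, quantile normalization, sample quality weights, no trend in the prior variance, the replicate number as a block, only the groups compared, a fold minimum of 2, and leaving out each library in turn. After seeing the data a correction was added that removes from each library a smooth trend (splines of 5 degrees of freedom) of the log2 values on transcript length and GC content. Lengths came from GENCODE M21 (GRCm38), which gave one for 13123 of the tested genes (95.4%). Gene positions came from the same annotation.

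The pipeline was tested on 13759 genes simulated independently for the WT cuprizone comparison. It recovered 52% of log2 changes of 0.5, 78% of 1 and 100% of 2 and 3. Of calls 4.07% were false, with correlated genes untested. A length trend added to another comparison gave 2709 calls and 10 after the length and GC correction, when 82.5% of WT changes passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.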

Results

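RNA of mouse corpus callosum, the broad tract of myelinated axons that joins the cerebral hemispheres, was sequenced in 12 libraries. The mice were wild type (WT) or lacked the aryl hydrocarbon receptor (AHR) in microglia, the resident macrophages of the brain, and are called AHR CKO here as in the labels. AHR is a transcription factor switched on by ligands such as tryptophan metabolites. Tissue of each genotype came from control mice and from the cuprizone model, in which this copper chelator kills oligodendrocytes, the myelin-forming cells, so that the corpus callosum loses myelin. The design gave 4 groups of 3 libraries and asked how loss of microglial AHR altered the tissue in this model. The deposited table listed FPKM (fragments scaled to transcript length and library size) for 15584 genes, of which 13759 were tested.

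FPKM values summed to between 447156 and 519470 per library. The lowest values gave an estimate of 11300000 to 14700000 fragments per library, from 11 to 36 genes each, within a range set after looking at them that by itself limits it to between 8330000 and 20000000. A 2 kb transcript at FPKM 1 would then rest on 22.7 to 29.4 fragments. This depth is a rough estimate and no counts were rebuilt. Across genes, libraries of 1 group correlated with r between 0.972 and 0.993, and libraries of different groups with r between 0.932 and 0.983. The first principal component held 44.82% of the variance and parted all cuprizone from all control libraries, and the next held 23.56% and parted WT from AHR CKO. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

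Ahr itself, on chromosome 12 at 35497974 to 35535038 (GRCm38), was low in all groups. It was listed at 1.78 ± 0.385 FPKM in WT control, 1.86 ± 0.141 in WT cuprizone, 1.76 ± 0.332 in AHR CKO control and 1.94 ± 0.567 in AHR CKO cuprizone (mean ± SD, n = 3). The difference between genotypes did not pass the test (averaged over treatments, log2 change 0.005, adjusted p = 0.98). This does not check the labels, since the whole tissue holds many cells outside the microglial lineage and the deleted part of the gene is not given in the sources used here. Of the AHR target genes that every comparison followed, Tiparp rose with cuprizone in WT from 5.11 ± 0.372 to 7.61 ± 0.778 FPKM (adjusted p = 0.00735). It was higher in AHR CKO than in WT control tissue at 7.78 ± 1.05 (adjusted p = 0.0307), which was lost without WT control replicate 1 or 2, WT cuprizone replicate 3 or AHR CKO control replicate 2 or 3 (largest adjusted p = 0.101). Cyp1b1 rose with cuprizone in AHR CKO from 0.791 ± 0.0806 to 3.38 ± 2.09 (adjusted p = 0.023). This call was lost without AHR CKO control replicate 1 or 2 or AHR CKO cuprizone replicate 2 or 3 (largest adjusted p = 0.0806). Cyp1b1 was 1.56 ± 0.572 against 0.609 ± 0.196 in WT (adjusted p = 0.155). The cuprizone effects on the 2 genes passed no interaction test (adjusted p = 0.361 for Tiparp and 0.753 for Cyp1b1). Nqo1, another AHR target, passed in none of the 6 comparisons, and Ahrr was not among the tested genes.

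Cuprizone lowered the myelin transcripts of WT corpus callosum. Mal, a proteolipid of compact myelin, fell from 522 ± 162 to 41.5 ± 6.59 FPKM (mean ± SD, n = 3, log2 change -3.58, adjusted p = 1.42e-06). Opalin, a membrane protein of oligodendrocytes, fell from 137 ± 42.9 to 13.9 ± 2.68 (log2 change -3.18, adjusted p = 3.15e-06), and Aspa, the oligodendrocyte enzyme that splits N-acetylaspartate, from 60.3 ± 14.9 to 5.74 ± 0.991 (log2 change -3.16, adjusted p = 1.93e-06). Of the 23 tested genes of mature oligodendrocytes and myelin, 0 rose, 21 fell and 2 did not pass the test (0 higher and 22 lower adjusted over the list alone), with a median log2 change of -2.05. The myelin list gave adjusted p = 3.21e-24, and adjusted p = 0.0838 with an estimated correlation. Fa2h, which hydroxylates the fatty acids of myelin galactolipids, fell from 105 ± 26.4 to 16.7 ± 3.82 FPKM. Klk6 and Ninj2, picked for the size of their change, fell from 18.5 ± 4.98 to 2.15 ± 1.58 and from 17.8 ± 8.18 to 0.957 ± 0.734. Of 9 transcription factors of the lineage, 0 rose, 5 fell and 4 did not pass the test (0 higher and 5 lower adjusted over the list alone). The lineage factor list gave adjusted p = 0.00466, and adjusted p = 0.337 with an estimated correlation. Nkx6-2 fell from 39.8 ± 11.5 to 12.6 ± 2.54 FPKM, Sox10 from 72.1 ± 17.2 to 41.03 ± 5.75 and Myrf, which drives myelin genes, from 38.4 ± 9.302 to 21.4 ± 3.897. The 14 precursor genes showed no call in either direction (adjusted p = 0.683), and of 12 genes of differentiating oligodendrocytes 1 rose, 1 fell and 10 did not pass the test (adjusted p = 0.0908).

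**Figure D1:**
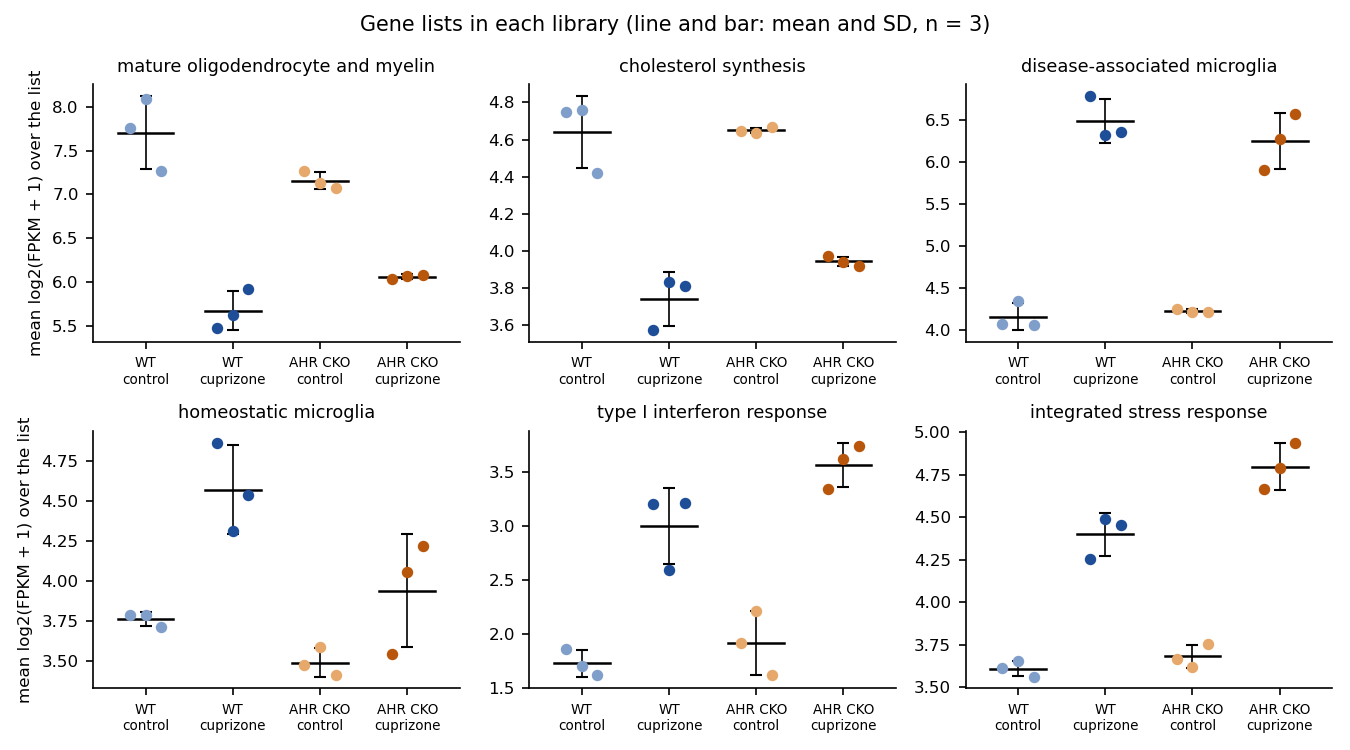
Mean log2(FPKM + 1) over the tested genes of 6 lists in each of the 12 libraries, with 1 point per library and the group mean and SD (n = 3) as a line and bar. The myelin list fell from 7.71 ± 0.41 in WT control to 5.67 ± 0.22 in WT cuprizone, and from 7.16 ± 0.10 to 6.06 ± 0.03 in AHR CKO.

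The genes of cholesterol synthesis fell with the myelin genes. Of 24, 0 rose, 22 fell and 2 did not pass the test (0 higher and 22 lower adjusted over the list alone), with a median log2 change of -0.87. The cholesterol list gave adjusted p = 2.93e-18, and adjusted p = 0.0838 with an estimated correlation. Msmo1, a sterol oxidase, fell from 78.02 ± 9.73 to 30.2 ± 2.49 FPKM (log2 change -1.34, adjusted p = 4.02e-06). Hmgcs1, which makes the precursor of mevalonate, fell from 127 ± 22.9 to 47.1 ± 5.404 (log2 change -1.40, adjusted p = 1.63e-05), and Insig1, the sterol sensor of the pathway, from 46.8 ± 6.86 to 14.4 ± 1.39 (log2 change -1.62, adjusted p = 5.2e-06). Genes of lipid efflux and storage went the other way, and of 16 10 rose, 1 fell and 5 did not pass the test (10 higher and 1 lower adjusted over the list alone). The lipid list gave adjusted p = 8.86e-08, and adjusted p = 0.0838 with an estimated correlation. Apoe, the main lipid carrier of the brain, rose 4.88-fold, from 2188 ± 284 to 10686 ± 1690 FPKM (log2 change 2.28, adjusted p = 1.27e-05). Plin2, a coat protein of lipid droplets, rose from 5.08 ± 0.648 to 16.6 ± 1.62, and Ch25h, which makes 25-hydroxycholesterol, from 0.317 ± 0.203 to 8.15 ± 3.47.

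Genes of activated microglia rose. Trem2, a lipid-sensing receptor of microglia, rose 7.46-fold, from 18.9 ± 1.28 to 141 ± 23.8 FPKM (log2 change 2.82, adjusted p = 1.42e-06). Itgax, which encodes CD11c, rose from 0.273 ± 0.232 to 19.99 ± 1.89 (73.1-fold). Clec7a, the receptor dectin-1, rose from 0.672 ± 0.574 to 38.6 ± 9.31 (57.5-fold) and Cst7, cystatin F, from 0.901 ± 0.814 to 73.9 ± 30.5 (82.1-fold). Spp1, osteopontin, rose from 8.76 ± 3.03 to 177 ± 74.8 and Lgals3, galectin-3, from 0.959 ± 0.4199 to 28.98 ± 5.84. Of the 27 disease-associated microglia genes 22 rose, 0 fell and 5 did not pass the test (24 higher and 0 lower adjusted over the list alone). The disease-associated microglia list gave adjusted p = 2.29e-27, and adjusted p = 0.0838 with an estimated correlation. The markers of homeostatic microglia did not fall as a group: of 17, 9 rose, 0 fell and 8 did not pass the test (9 higher and 1 lower adjusted over the list alone). The homeostatic microglia list gave adjusted p = 6.89e-06, and adjusted p = 0.232 with an estimated correlation. Fcrls rose from 12.9 ± 1.02 to 70.99 ± 17.6 FPKM and Csf1r, the receptor that keeps microglia alive, from 33.9 ± 1.304 to 102 ± 21.3.

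Phagocytic, lysosomal and complement genes moved with them, and some genes stand in more than 1 of these lists. Of 34 phagocytosis genes 20 rose, 3 fell and 11 did not pass the test (22 higher and 6 lower adjusted over the list alone). The phagocytosis list gave adjusted p = 4.59e-12, and adjusted p = 0.108 with an estimated correlation. Tyrobp, the signalling partner of Trem2, rose 8.22-fold and Fcer1g, the common chain of Fc receptors, from 21.2 ± 4.17 to 135 ± 37.4 FPKM. Of 33 lysosome genes 24 rose, 1 fell and 8 did not pass the test (25 higher and 2 lower adjusted over the list alone). The lysosome list gave adjusted p = 2.04e-16, and adjusted p = 0.108 with an estimated correlation. The protease Ctsd rose from 232 ± 21.9 to 1208 ± 320.4 FPKM, Cd68 from 13.1 ± 3.78 to 101 ± 27.9 and the progranulin gene Grn from 30.2 ± 1.49 to 142 ± 43.8. Of 15 complement genes 11 rose, 0 fell and 4 did not pass the test (11 higher and 0 lower adjusted over the list alone). The complement list gave adjusted p = 9.9e-11, and adjusted p = 0.108 with an estimated correlation. C1qa and C1qb, which encode chains of C1q, rose from 73.3 ± 8.79 to 435 ± 93.3 and from 61.9 ± 6.18 to 344 ± 60.3, and the receptor C3ar1 from 0.986 ± 0.191 to 11.2 ± 2.49.

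Antigen presentation, interferon and chemokine genes rose as well. Of 14 genes of MHC class I and antigen processing 13 rose, 0 fell and 1 did not pass the test (14 higher and 0 lower adjusted over the list alone). The class I list gave adjusted p = 1.8e-16, and adjusted p = 0.0838 with an estimated correlation. H2-D1 rose from 34.6 ± 3.87 to 201 ± 54.9 FPKM, B2m from 202 ± 15.8 to 972 ± 301 and Psmb8, an immunoproteasome subunit, from 4.15 ± 0.401 to 21.7 ± 4.34. All 6 class II genes tested rose (adjusted p = 5.05e-07, and adjusted p = 0.108 with an estimated correlation), Cd74 among them from 3.59 ± 1.13 to 102 ± 58.97 and H2-Aa from 0.602 ± 0.127 to 23.4 ± 15.2. Of 32 type I interferon genes 24 rose, 0 fell and 8 did not pass the test (27 higher and 0 lower adjusted over the list alone). The interferon list gave adjusted p = 1.5e-18, and adjusted p = 0.108 with an estimated correlation. Lgals3bp rose from 8.12 ± 1.303 to 104 ± 38.2 FPKM and Oas1a from 0.342 ± 0.165 to 3.86 ± 1.43. Of 20 cytokine, chemokine and NF-kB genes 17 rose, 1 fell and 2 did not pass the test (18 higher and 1 lower adjusted over the list alone). The cytokine list gave adjusted p = 1.8e-14, and adjusted p = 0.0838 with an estimated correlation. The chemokine gene Ccl3 rose from 1.19 ± 0.695 to 26.9 ± 0.474, Cxcl16 from 0.632 ± 0.0936 to 9.63 ± 1.12 and the receptor Tlr2 from 0.714 ± 0.164 to 9.52 ± 2.54.

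Astrocyte and stress genes changed too. Serpina3n, a marker of reactive astrocytes, rose 18.3-fold, from 7.698 ± 1.92 to 141 ± 47.9 FPKM (log2 change 4.003, adjusted p = 5.2e-06). The intermediate filament genes Gfap and Vim rose from 185 ± 57.8 to 1083 ± 169 and from 43.2 ± 9.29 to 293 ± 77.1. Of 22 reactive astrocyte genes 17 rose, 0 fell and 5 did not pass the test (20 higher and 0 lower adjusted over the list alone). The reactive astrocyte list gave adjusted p = 2.01e-18, and adjusted p = 0.0838 with an estimated correlation. Of 18 homeostatic astrocyte genes 7 rose, 0 fell and 11 did not pass the test (11 higher and 0 lower adjusted over the list alone). The homeostatic astrocyte list gave adjusted p = 4.44e-05, and adjusted p = 0.0838 with an estimated correlation. Mlc1 rose from 110.5 ± 6.36 to 208 ± 21.96. Of 23 integrated stress response genes 13 rose, 1 fell and 9 did not pass the test (14 higher and 1 lower adjusted over the list alone). The stress response list gave adjusted p = 8.73e-09, and adjusted p = 0.0838 with an estimated correlation. The transcription factors Atf5 and Atf3 rose from 19.03 ± 3.5 to 116 ± 28.4 and from 0.627 ± 0.119 to 7.55 ± 0.726 FPKM. Of 14 immediate early genes 6 rose, 0 fell and 8 did not pass the test (8 higher and 0 lower adjusted over the list alone). The immediate early list gave adjusted p = 2.16e-06, and adjusted p = 0.183 with an estimated correlation. Egr2 rose from 1.097 ± 0.1003 to 6.54 ± 1.28. Hmox1, haem oxygenase 1, rose from 3.63 ± 0.824 to 18.5 ± 0.631, while of the 17 antioxidant and metal-binding genes 6 rose, 2 fell and 9 did not pass the test (adjusted p = 0.0908).

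Other cell types were measured beside these groups in WT. None of 20 neuron genes, 14 endothelial genes or 22 cell cycle genes passed. Snap25, a synaptic protein gene, stood at 848 ± 183 against 1102 ± 73.7 FPKM (adjusted p = 0.132) and Slc2a1, the glucose transporter of brain vessels, at 60.2 ± 4.71 against 69.5 ± 8.58 (adjusted p = 0.224). The striatal list was lower with no single call (adjusted p = 0.00814, and adjusted p = 0.588 with an estimated correlation), a call lost without WT control replicate 3 or WT cuprizone replicate 2 (largest adjusted p = 0.247). The choroid plexus list was higher with no single call (adjusted p = 0.0205, and adjusted p = 0.635 with an estimated correlation), lost without WT control replicate 1 or WT cuprizone replicate 1 or 3 (largest adjusted p = 0.266). Its marker Ttr stood at 2919, 54.3 and 958 FPKM in the 3 WT cuprizone libraries, a wide spread within 1 group. The fibroblast list (adjusted p = 0.0322, and adjusted p = 0.56 with an estimated correlation) had 2 higher genes and was lost without WT control replicate 1 or WT cuprizone replicate 1 (largest adjusted p = 0.188). The AHR target list had 2 higher genes, Tiparp and Ugt1a6a (adjusted p = 0.0315, and adjusted p = 0.139 with an estimated correlation), and was lost without WT control replicate 1 or WT cuprizone replicate 3 (largest adjusted p = 0.0785). The border macrophage list (4 tested, 1 higher) was called at adjusted p = 0.0214, and adjusted p = 0.183 with an estimated correlation. This call and that of the fibroblast list ended after a length and GC correction (adjusted p = 0.0531 for each).

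In all, cuprizone changed 2324 genes in WT, 1249 higher and 1075 lower (limma, Benjamini-Hochberg, adjusted p threshold 0.05), of which 459 higher and 223 lower changed at least 2-fold. All 3 libraries of 1 group lay above all 3 of the other in 34.7% of the tested genes, where chance gives 10%, and in every gene named here as risen or fallen. An exact permutation test of 3 against 3 cannot go below p = 0.1. Leaving out any 1 of the 12 libraries moved the count within 1594 to 2439, and 55 of the 56 named calls held each time. No list call in any comparison was kept when the correlation between genes was estimated.

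In AHR CKO mice, cuprizone again lowered myelin genes and raised microglial, interferon and chemokine genes. Mal fell from 342 ± 21.7 to 62.7 ± 7.55 FPKM (mean ± SD, n = 3, log2 change -2.43, adjusted p = 1.44e-05). Mog, which encodes a myelin surface protein, fell from 124 ± 11.1 to 43.97 ± 4.56. Cxcl10, an interferon-induced chemokine, rose 149-fold, from 0.262 ± 0.118 to 39.2 ± 10.1 (log2 change 4.96, adjusted p = 1.22e-05), and Ccl5 from 0.609 ± 0.282 to 22.1 ± 5.84 (36.3-fold). All 32 type I interferon genes tested rose, with a median log2 change of 1.59 (adjusted p = 9.16e-32, and adjusted p = 0.0646 with an estimated correlation). Ifit3 rose from 6.68 ± 1.16 to 50.3 ± 5.48 FPKM, Oasl2 from 2.29 ± 0.773 to 23.03 ± 3.53 and the guanylate-binding protein gene Gbp3 from 4.44 ± 1.35 to 19.7 ± 2.46. All 14 genes of MHC class I and antigen processing rose as well (adjusted p = 3.92e-19, and adjusted p = 0.0511 with an estimated correlation), Psmb8 from 4.55 ± 0.764 to 28.9 ± 5.82 and H2-D1 from 41.3 ± 1.45 to 242 ± 63.9. Of 20 cytokine, chemokine and NF-kB genes 15 rose, 0 fell and 5 did not pass the test (17 higher and 0 lower adjusted over the list alone). The cytokine list gave adjusted p = 3.56e-15, and adjusted p = 0.0726 with an estimated correlation. Of 6 class II genes 5 rose, 0 fell and 1 did not pass the test (adjusted p = 6.24e-06, and adjusted p = 0.147 with an estimated correlation), Cd74 from 5.61 ± 3.51 to 88.1 ± 37.6.

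Activated microglia genes rose in AHR CKO as well. Trem2 rose from 20.9 ± 2.79 to 110.3 ± 20.3 FPKM (5.27-fold, log2 change 2.33, adjusted p = 5.5e-06). Itgax rose from 0.166 ± 0.13 to 12.3 ± 4.54 (74.3-fold), Clec7a from 0.461 ± 0.111 to 26.9 ± 9.87 (58.4-fold) and Lgals3 from 1.55 ± 0.392 to 39.3 ± 14.3 (25.3-fold). Of 27 disease-associated microglia genes 24 rose, 0 fell and 3 did not pass the test (25 higher and 0 lower adjusted over the list alone). The disease-associated microglia list gave adjusted p = 1.11e-30, and adjusted p = 0.0528 with an estimated correlation. Of 34 phagocytosis genes 17 rose, 1 fell and 16 did not pass the test (19 higher and 3 lower adjusted over the list alone). The phagocytosis list gave adjusted p = 1.31e-11, and adjusted p = 0.134 with an estimated correlation. Of 33 lysosome genes 18 rose, 1 fell and 14 did not pass the test (25 higher and 2 lower adjusted over the list alone). The lysosome list gave adjusted p = 5.8e-14, and adjusted p = 0.149 with an estimated correlation. Ctss rose from 83.96 ± 6.46 to 398 ± 132 and Ctsd from 249 ± 16.4 to 751 ± 147. Of 15 complement genes 10 rose, 0 fell and 5 did not pass the test (13 higher and 0 lower adjusted over the list alone). The complement list gave adjusted p = 2.03e-12, and adjusted p = 0.0903 with an estimated correlation. C4b rose from 6.71 ± 1.59 to 49.2 ± 12.1. Of 17 homeostatic microglia genes 5 rose, 1 fell and 11 did not pass the test (6 higher and 2 lower adjusted over the list alone). The homeostatic microglia list gave adjusted p = 0.02, and adjusted p = 0.608 with an estimated correlation. It was lost without AHR CKO control replicate 3 or AHR CKO cuprizone replicate 2 or 3 (largest adjusted p = 0.0893). Fcrls rose from 11.9 ± 1.47 to 36.5 ± 10 and Csf1r from 28.5 ± 1.88 to 63.8 ± 21.5.

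Glial, lipid and stress genes followed. Of 23 myelin genes 0 rose, 19 fell and 4 did not pass the test (0 higher and 20 lower adjusted over the list alone). The myelin list gave adjusted p = 1.57e-17, and adjusted p = 0.134 with an estimated correlation. Of 24 cholesterol synthesis genes 0 rose, 17 fell and 7 did not pass the test (0 higher and 22 lower adjusted over the list alone). The cholesterol list gave adjusted p = 3.92e-19, and adjusted p = 0.0726 with an estimated correlation. Msmo1 fell from 77.3 ± 0.272 to 35.3 ± 0.889. Of 16 lipid efflux and storage genes 9 rose, 0 fell and 7 did not pass the test (13 higher and 0 lower adjusted over the list alone). The lipid list gave adjusted p = 2.81e-10, and adjusted p = 0.0528 with an estimated correlation. Apoe rose from 3210.3 ± 328 to 11720.1 ± 2207 and Abca1, a cholesterol exporter, from 5.17 ± 1.09 to 18.4 ± 6.56. Of 22 reactive astrocyte genes 18 rose, 0 fell and 4 did not pass the test (20 higher and 0 lower adjusted over the list alone). The reactive astrocyte list gave adjusted p = 1.04e-20, and adjusted p = 0.0511 with an estimated correlation. Gfap rose from 161 ± 8.92 to 1001 ± 275 FPKM and Tgm1, a transglutaminase, from 0.113 ± 0.0562 to 14.1 ± 6.69 (125-fold). Of 23 integrated stress response genes 16 rose, 0 fell and 7 did not pass the test (19 higher and 2 lower adjusted over the list alone). The stress response list gave adjusted p = 3.05e-16, and adjusted p = 0.0511 with an estimated correlation. Trib3, a target of this response, rose 24.8-fold, from 0.458 ± 0.155 to 11.3 ± 0.542, and Eif4ebp1, an inhibitor of translation, from 4.57 ± 0.312 to 23.8 ± 4.18. Of 17 antioxidant and metal-binding genes 5 rose, 0 fell and 12 did not pass the test (adjusted p = 0.00033, and adjusted p = 0.0511 with an estimated correlation), Hmox1 from 3.3 ± 0.369 to 24.8 ± 6.64.

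Among the other lists in AHR CKO, 18 homeostatic astrocyte genes had 4 that rose (adjusted p = 0.0286, and adjusted p = 0.317 with an estimated correlation), lost without AHR CKO control replicate 3 or cuprizone replicate 2 (largest adjusted p = 0.144). The 20 neuron genes had no call but a list call below the rest (adjusted p = 0.0465, and adjusted p = 0.529 with an estimated correlation), lost without AHR CKO control replicate 3 or cuprizone replicate 3 (largest adjusted p = 0.267) and after that correction (0.0601). The striatal (adjusted p = 0.114), choroid plexus (adjusted p = 0.932) and immediate early (adjusted p = 0.895) lists were not called, and Egr1 was 127 ± 27.8 against 165 ± 2.89 FPKM (adjusted p = 0.267). In all, 1403 genes changed, 993 higher and 410 lower by limma, so 70.8% of calls were higher, against 59.0% after rescaling to a common total and 60.1% after quantile normalization. All 3 libraries of 1 group lay above all 3 of the other in 28.9% of the tested genes, against 10% by chance. The count fell to 840 without AHR CKO control replicate 1 and to 872 without AHR CKO control replicate 2, and log2 change fell with transcript length across genes (Spearman -0.38, against -0.162 in WT).

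Cuprizone changes overlapped between genotypes, which share 1 estimate of the spread but no libraries. Of 1249 genes higher in WT and 993 in AHR CKO, 758 were shared, where independent lists, which these are not, would share 90.1. Of the lower genes 295 were shared against 32, and 1 gene was called in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated with Pearson r 0.783 and Spearman rho 0.574. Of the 2673 genes called in either genotype, 92% had the same sign in both. That more genes passed in WT does not show a stronger response there, since the difference itself passed in only 5 genes, given with the interaction.

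**Figure D2:**
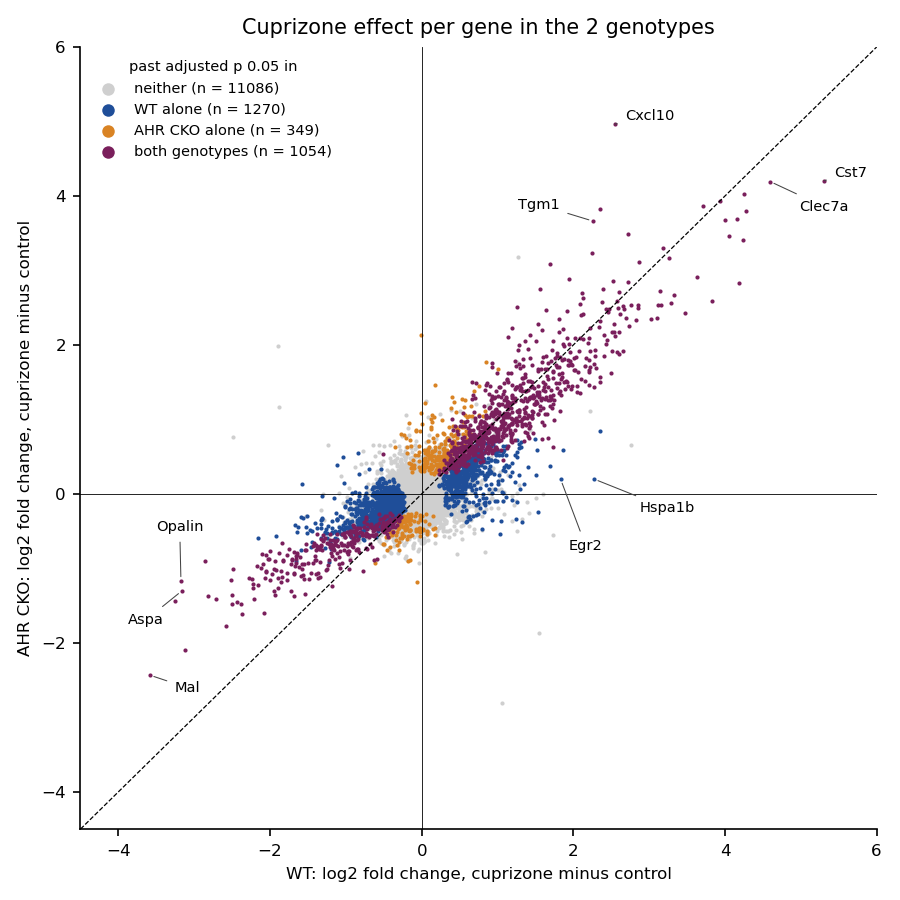
Each point is 1 of the 13759 tested genes, with its cuprizone log2 fold change in WT on the horizontal axis and in AHR CKO on the vertical axis, coloured by the genotypes in which limma called it. Most called genes lie along the diagonal of equal change, while Opalin and Aspa fell further in WT and Egr2 and Hspa1b rose in WT alone.

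The genotypes were compared within cuprizone tissue, which is the question named in the study's design. Opalin was 3.89-fold higher in AHR CKO at 54.3 ± 9.03 against 13.9 ± 2.68 FPKM (mean ± SD, n = 3, log2 change 1.89, adjusted p = 0.00125). Aspa was 2.33-fold higher at 13.4 ± 0.904 against 5.74 ± 0.991 (log2 change 1.10, adjusted p = 0.00565). Some interferon genes were higher in AHR CKO. Irf7, a master regulator of interferon genes, stood at 24.1 ± 3.19 against 9.74 ± 3.71 (log2 change 1.29, adjusted p = 0.014) and Ifit3 at 50.3 ± 5.48 against 23.2 ± 7.904 (log2 change 1.13, adjusted p = 0.0114). Some homeostatic microglia genes and the phagocytic receptor Mertk were lower. Gpr34 stood at 15.4 ± 4.22 against 29.6 ± 5.83 (log2 change -0.92, adjusted p = 0.00954), Fcrls at 36.5 ± 10 against 70.99 ± 17.6 (log2 change -0.95, adjusted p = 0.00993) and Mertk at 9.68 ± 2.83 against 17.2 ± 2.45 (log2 change -0.80, adjusted p = 0.0119). Hspa1b, an inducible heat shock protein gene, stood at 2.88 ± 0.222 against 14.8 ± 4.75 (log2 change -1.98, adjusted p = 0.000868). These differences stand beside a length trend: the median log2 change was 0.347 for transcripts of up to 1000 nt and -0.291 for those over 6000 nt.

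Of 17 homeostatic microglia genes 0 were higher, 7 lower and 10 did not pass the test (0 higher and 12 lower adjusted over the list alone), with a median log2 change of -0.56. The homeostatic microglia list gave adjusted p = 0.00011, and adjusted p = 0.796 with an estimated correlation. Crybb1 was lower at 2.16 ± 0.415 against 5.38 ± 1.34 FPKM. Cx3cr1, the fractalkine receptor of microglia, was 17.8 ± 14.8 against 59.1 ± 10.01 (log2 change -2.36, adjusted p = 0.069) and did not pass, with 1.16, 22.7 and 29.6 FPKM in the 3 AHR CKO libraries. Of 34 phagocytosis genes 1 was higher, 5 lower and 28 did not pass the test (1 higher and 7 lower adjusted over the list alone). The phagocytosis list gave adjusted p = 0.00187, and adjusted p = 0.796 with an estimated correlation. Fcgr3, an Fc receptor, was lower at 44.97 ± 13.96 against 77.7 ± 18.8 (adjusted p = 0.0256), a call lost without WT cuprizone replicate 1 or 3 or AHR CKO cuprizone replicate 1 (largest adjusted p = 0.0924). Of 33 lysosome genes 0 were higher, 8 lower and 25 did not pass the test (0 higher and 8 lower adjusted over the list alone). The lysosome list gave adjusted p = 0.00102, and adjusted p = 0.796 with an estimated correlation. The proton pump subunit gene Atp6v1a stood at 85.5 ± 1.94 against 112 ± 10.3 (adjusted p = 0.0107). Of 27 disease-associated microglia genes 1 was higher, 4 lower and 22 did not pass the test (1 higher and 4 lower adjusted over the list alone), adjusted p = 0.0983 for the list. Ccl6, a chemokine, stood at 20.2 ± 6.21 against 45.8 ± 6.85 (adjusted p = 0.00717) and Fabp5, a fatty acid carrier, higher at 164 ± 6.005 against 114 ± 7.69 (adjusted p = 0.00688). After a length and GC correction chosen after seeing the data, this last list was called as lower (adjusted p = 0.01).

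Of 32 type I interferon genes 15 were higher, 0 lower and 17 did not pass the test (17 higher and 0 lower adjusted over the list alone), with a median log2 change of 0.60. The interferon list gave adjusted p = 3.64e-06, and adjusted p = 0.796 with an estimated correlation. Gbp3 was higher at 19.7 ± 2.46 against 10.1 ± 0.787 FPKM (adjusted p = 0.00808) and Cxcl10 at 39.2 ± 10.1 against 11.6 ± 3.82 (adjusted p = 0.0137), a call lost with a pseudocount of 0.1. Of 23 integrated stress response genes 10 were higher, 0 lower and 13 did not pass the test (12 higher and 0 lower adjusted over the list alone). The stress response list gave adjusted p = 0.00011, and adjusted p = 0.762 with an estimated correlation. Trib3 was 2.46-fold higher at 11.3 ± 0.542 against 4.62 ± 1.24. Eif4ebp1 stood at 23.8 ± 4.18 against 12.7 ± 1.93, Asns, asparagine synthetase, at 47.1 ± 1.13 against 32.9 ± 2.46 and Ppp1r15a, which restores translation after stress, at 13 ± 1.02 against 8.04 ± 0.966. Of 14 genes of MHC class I and antigen processing 2 were higher, 0 lower and 12 did not pass the test (adjusted p = 0.0122, and adjusted p = 0.796 with an estimated correlation). This list call was lost without WT cuprizone replicate 2 or AHR CKO cuprizone replicate 3 (largest adjusted p = 0.161) and after the correction for length and GC (adjusted p = 0.0823). The class II gene Cd74 was 88.1 ± 37.6 against 102 ± 58.97 (adjusted p = 0.935).

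Of 23 myelin genes 3 were higher, 0 lower and 20 did not pass the test (6 higher and 0 lower adjusted over the list alone). The myelin list gave adjusted p = 0.00268, and adjusted p = 0.796 with an estimated correlation. The transcription factor Nkx6-2 was higher at 31.2 ± 5.84 against 12.6 ± 2.54 FPKM (log2 change 1.25, adjusted p = 0.00578). Of 24 cholesterol synthesis genes 8 were higher, 1 lower and 15 did not pass the test (9 higher and 1 lower adjusted over the list alone). The cholesterol list gave adjusted p = 0.0107, and adjusted p = 0.796 with an estimated correlation. It was lost without WT cuprizone replicate 1 (adjusted p = 0.1). Insig1 stood at 24.2 ± 2.88 against 14.4 ± 1.39 (adjusted p = 0.00573). Tnr, tenascin-R, was lower at 3.96 ± 1.47 against 11.2 ± 1.78 (adjusted p = 0.00387) and Xylt1, which starts proteoglycan chains, at 1.83 ± 0.834 against 5.196 ± 0.626 (adjusted p = 0.00877). The precursor list was not called (adjusted p = 0.672) and its median of 0.09 had the opposite sign to its mean. Slc1a2, the main astrocyte glutamate transporter, was lower at 198 ± 44.5 against 349 ± 13.5 (adjusted p = 0.0072). The homeostatic astrocyte list had 5 lower genes (adjusted p = 0.0445, and adjusted p = 0.796 with an estimated correlation), lost without WT cuprizone replicate 1 or 2 or AHR CKO cuprizone replicate 3 (largest adjusted p = 0.103). The antioxidant list had 1 higher gene (adjusted p = 0.0472, and adjusted p = 0.762 with an estimated correlation). It was lost in 5 of 12 leave-one-out fits, those without WT control replicate 1, WT cuprizone replicate 2 or 3, AHR CKO control replicate 1 or AHR CKO cuprizone replicate 3 (largest adjusted p = 0.108), and after the length and GC correction (0.278). No AHR target gene passed (adjusted p = 0.338 for the list).

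Markers of blood and of tissue bordering the corpus callosum differed as well. All 3 red blood cell genes tested were lower in AHR CKO cuprizone tissue (adjusted p = 0.00175, and adjusted p = 0.617 with an estimated correlation). The haemoglobin gene Hba-a2 stood at 0.0527 ± 0.0737 against 25.5 ± 10.8 FPKM (log2 change -4.58, adjusted p = 0.00118) and Alas2, the haem synthesis enzyme of red cells, at 0.0987 ± 0.171 against 2.09 ± 1.15. Reads of the haemoglobin genes may be split between near-identical copies, so their single values are uncertain. Of 11 fibroblast and meningeal genes 3 were higher, 0 lower and 8 did not pass the test (5 higher and 0 lower adjusted over the list alone). The fibroblast list gave adjusted p = 0.00163, and adjusted p = 0.796 with an estimated correlation. The ependymal list was higher (adjusted p = 0.0211, and adjusted p = 0.796 with an estimated correlation), lost without WT cuprizone replicate 2 (adjusted p = 0.149) and after the length and GC correction (adjusted p = 0.0676). The striatal list was higher with no single call (adjusted p = 0.0213, and adjusted p = 0.796 with an estimated correlation), lost without WT cuprizone replicate 2 or AHR CKO cuprizone replicate 1 or 2 (largest adjusted p = 0.13). Vtn, a gene of pericytes, was higher at 64.9 ± 6.41 against 34.95 ± 1.802 (adjusted p = 0.00283), and Dok6, picked for its size, lower at 2.65 ± 1.26 against 16.7 ± 3.86 (adjusted p = 0.00199).

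In all, 2747 genes differed between genotypes in cuprizone tissue, 1257 higher and 1490 lower in AHR CKO by limma, of which 166 differed at least 2-fold. All 3 libraries of 1 group lay above all 3 of the other in 38.8% of tested genes, against 10% by chance. Higher genes were 45.8% of the calls, against 21.2% after rescaling to a common total, which moved the median of all genes to -0.12. The count was 1148 without WT cuprizone replicate 1, 1201 without WT cuprizone replicate 3, 777 without AHR CKO cuprizone replicate 1 and 1474 without AHR CKO cuprizone replicate 2. It was 1066 after correcting each library for transcript length and GC, and 857 genes were called in both. Of the 58 named calls, 38 held in all 12 leave-one-out fits, and of the other 20 only Fcgr3 is given above for this comparison. After that correction 13 were lost, none of them given above for it.

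Without cuprizone, immediate early genes were higher in AHR CKO tissue. Egr2, a zinc finger transcription factor, stood at 6.32 ± 0.636 against 1.097 ± 0.1003 FPKM (mean ± SD, n = 3, 5.76-fold, log2 change 1.80, adjusted p = 0.000565). Junb stood at 104 ± 14.8 against 31.6 ± 3.54 (3.296-fold, log2 change 1.69, adjusted p = 0.0019), Egr4 at 53.1 ± 3.27 against 15.2 ± 4.13 (log2 change 1.77, adjusted p = 0.00951) and Fos at 23.8 ± 2.498 against 7.04 ± 2.71 (log2 change 1.68, adjusted p = 0.0164). Of 14 immediate early genes 10 were higher, 0 lower and 4 did not pass the test (12 higher and 0 lower adjusted over the list alone), with a median log2 change of 0.96. The immediate early list gave adjusted p = 4.35e-12, and adjusted p = 0.339 with an estimated correlation. Of 23 myelin genes 0 were higher, 3 lower and 20 did not pass the test (0 higher and 13 lower adjusted over the list alone). The myelin list gave adjusted p = 1.89e-06, and adjusted p = 0.89 with an estimated correlation. Ermn, a cytoskeletal gene of oligodendrocytes, stood at 57.98 ± 6.36 against 116 ± 32.3 (log2 change -0.96, adjusted p = 0.0359). Anln stood at 15.97 ± 1.43 against 37.02 ± 10.3 (adjusted p = 0.0288), Aspa at 34.9 ± 6.56 against 60.3 ± 14.9 (adjusted p = 0.0384) and the regulator Myrf at 21.9 ± 2.14 against 38.4 ± 9.302 (adjusted p = 0.0338). These 4 calls were lost without WT control replicate 1 or 2 or AHR CKO control replicate 2 or 3, all but that of Anln also without AHR CKO cuprizone replicate 2, and those of Aspa and Myrf without WT cuprizone replicate 3 (largest adjusted p = 0.153). That of Fos was lost without WT control replicate 2 or AHR CKO control replicate 2 or 3 (largest adjusted p = 0.0892) and that of Egr4 without AHR CKO control replicate 3 (adjusted p = 0.0717).

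Neither microglial list passed the test in control tissue. None of the 17 homeostatic microglia genes passed (adjusted p = 0.428 for the list), nor did any of the 27 disease-associated ones (adjusted p = 0.351). Csf1r was 28.5 ± 1.88 against 33.9 ± 1.304 FPKM (adjusted p = 0.492) and C1qa 76.2 ± 5.12 against 73.3 ± 8.79 (adjusted p = 0.856). Cx3cr1, on chromosome 9 at 119901616 to 120069879 (GRCm38), was 3.82 ± 5.01 against 23.95 ± 1.2 (log2 change -2.88, adjusted p = 0.0634) and did not pass, with 1.05, 9.60 and 0.801 FPKM in the 3 AHR CKO libraries. Of 34 phagocytosis genes 1 was higher, 2 lower and 31 did not pass the test (adjusted p = 0.492). Gas6, the ligand of Mertk, was higher at 58 ± 5.97 against 42.8 ± 1.12 (adjusted p = 0.0363) and Megf10, an engulfment receptor of astrocytes, lower at 7.36 ± 0.9803 against 11.6 ± 1.96 (adjusted p = 0.0348). Of 33 lysosome genes 0 were higher, 2 lower and 31 did not pass the test (adjusted p = 0.828), one of them Npc1, a cholesterol exporter of lysosomes, at 23.1 ± 1.93 against 35.2 ± 6.81 (adjusted p = 0.0395). The calls of Gas6, Megf10 and Npc1 were lost without WT control replicate 1 or 2, WT cuprizone replicate 3, AHR CKO control replicate 2 or 3 or AHR CKO cuprizone replicate 2 (largest adjusted p = 0.15). The 32 interferon genes showed no call (adjusted p = 0.0779), and the MHC class I list was higher with 1 call (adjusted p = 0.00231, and adjusted p = 0.89 with an estimated correlation).

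Blood and border tissue markers differed in control tissue too. Hba-a2 stood at 0.2002 ± 0.323 against 19.1 ± 12.6 FPKM (log2 change -3.79, adjusted p = 0.012) and Hba-a1 at 4.76 ± 1.19 against 92.5 ± 18.2 (log2 change -4.02, adjusted p = 0.031). Alas2 was listed at 0 in all 3 AHR CKO control libraries and at 1.51 ± 0.221 in WT. The red blood cell list had all 3 genes lower (adjusted p = 0.000927, and adjusted p = 0.339 with an estimated correlation). Of 11 fibroblast and meningeal genes 4 were higher, 0 lower and 7 did not pass the test (10 higher and 0 lower adjusted over the list alone). The fibroblast list gave adjusted p = 1.82e-08, and adjusted p = 0.424 with an estimated correlation. The collagen genes stood higher, Col1a1 at 2.82 ± 0.18 against 1.099 ± 0.0466 (adjusted p = 0.0227) and Col1a2 at 3.54 ± 0.251 against 1.43 ± 0.219 (adjusted p = 0.0193). The binding protein gene Igfbp2 stood at 56.7 ± 18.4 against 13.4 ± 2.54 (adjusted p = 0.0272). The choroid plexus list was higher with no call over all genes and 4 adjusted over the list alone (adjusted p = 2.14e-05, and adjusted p = 0.89 with an estimated correlation). Ttr, the transthyretin gene of choroid plexus, stood at 1914 ± 1547 against 88.7 ± 52.4 (adjusted p = 0.0611). Without AHR CKO control replicate 2 or 3 the calls of Hba-a2 (largest adjusted p = 0.0736), Hba-a1, Alas2, Col1a1, Col1a2 and Igfbp2 were lost. Those other than Hba-a2 were also lost without WT control replicate 1 or 2, and Hba-a1 without WT cuprizone replicate 3 (largest adjusted p = 0.121). Striatal genes did not pass the test (adjusted p = 0.248).

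In all, 851 genes differed in control tissue, 196 higher and 655 lower in AHR CKO by limma, so 23% of calls were higher, against 32.9% after quantile normalization. All 3 libraries of 1 group lay above all 3 of the other in 35.4% of tested genes, against 10% by chance. This count rested on single libraries: it was 8 without WT control replicate 1, 12 without WT control replicate 2, 179 without WT cuprizone replicate 3, 7 without AHR CKO control replicate 2, 4 without AHR CKO control replicate 3, 259 without AHR CKO cuprizone replicate 2 and 1428 without AHR CKO cuprizone replicate 1. Egr2 and Junb were the 2 of 37 named calls that held in all 12 of these fits. The median log2 change fell from 0.251 for transcripts of up to 1000 nt to -0.264 for those over 6000 nt, and after the length and GC correction 60 genes were called, 53 of them among the 851. Of the 37 named calls 23 were lost after it, among them those of Ermn, Anln, Aspa, Myrf, Gas6, Megf10, Npc1, Hba-a1 and Igfbp2.

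**Figure D3:**
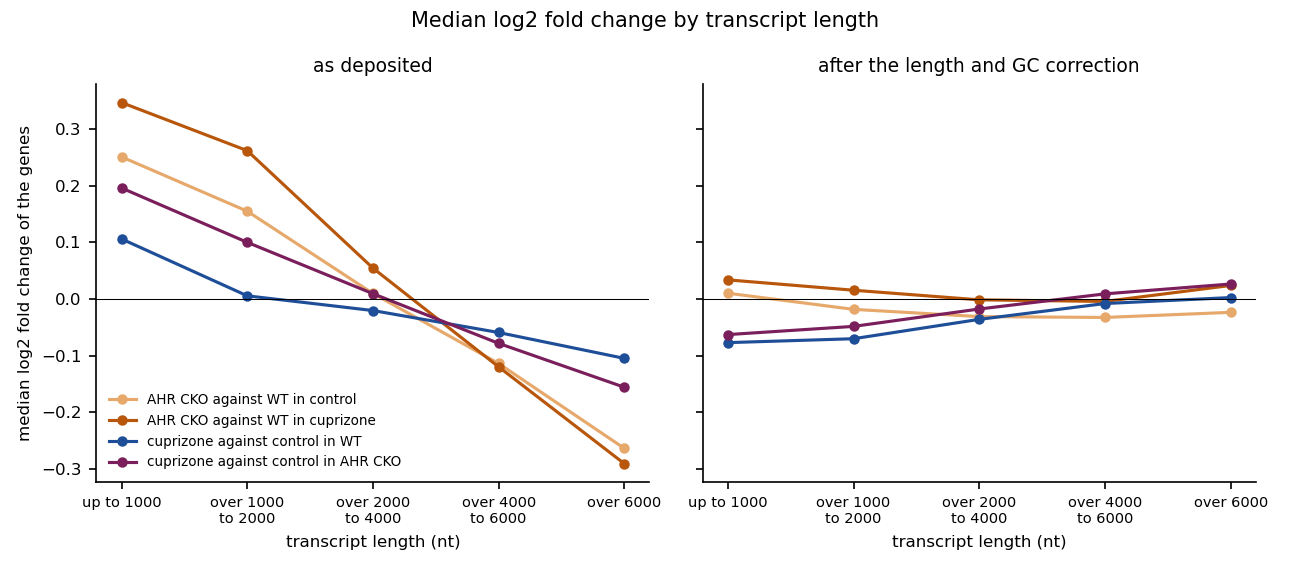
Median log2 fold change of the tested genes in 5 classes of transcript length (nt), for 4 comparisons, as deposited on the left and after the length and GC correction on the right. In the 2 genotype comparisons the medians fell with length from 0.347 to -0.291 (cuprizone) and from 0.251 to -0.264 (control), and lay near 0 after the correction.

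The interaction asked whether the cuprizone effect differed between genotypes, and 5 genes passed. Opalin (chromosome 19, 41061710 to 41077113, GRCm38) fell less with cuprizone in AHR CKO, from 122 ± 1.64 to 54.3 ± 9.03 FPKM, than in WT, from 137 ± 42.9 to 13.9 ± 2.68 (mean ± SD, n = 3, interaction 2.01 on the log2 scale, adjusted p = 0.0465). Aspa (chromosome 11, 73304992 to 73329596) fell from 34.9 ± 6.56 to 13.4 ± 0.904 in AHR CKO and from 60.3 ± 14.9 to 5.74 ± 0.991 in WT (interaction 1.86, adjusted p = 0.0398). Hspa5 (chromosome 2, 34771970 to 34777547), the main chaperone of the endoplasmic reticulum, rose in WT from 118 ± 10.8 to 251 ± 28.1 (adjusted p = 1.65e-05) and was 100.1 ± 5.08 and 93.3 ± 4.26 in AHR CKO (adjusted p = 0.576, interaction -1.18, adjusted p = 0.0277). Hspa1b (chromosome 17, 34956436 to 34959238) rose in WT from 2.18 ± 0.253 to 14.8 ± 4.75 and was 2.44 ± 0.811 and 2.88 ± 0.222 in AHR CKO (interaction -2.08, adjusted p = 0.0398). Egr2 (chromosome 10, 67535475 to 67542188) rose in WT from 1.097 ± 0.1003 to 6.54 ± 1.28 and was already at 6.32 ± 0.636 in AHR CKO control and at 7.45 ± 1.47 after cuprizone (interaction -1.64, adjusted p = 0.0329).

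Of 23 myelin genes, 2 passed the interaction test in the direction of a smaller fall in AHR CKO and 21 did not pass (18 higher and 0 lower adjusted over the list alone), with a median of 0.90. The myelin list gave adjusted p = 1.15e-17, and adjusted p = 0.595 with an estimated correlation. Of 14 immediate early genes 1 passed, in the direction of a smaller rise (0 higher and 5 lower adjusted over the list alone). The immediate early list gave adjusted p = 8.67e-10 (0.595 with an estimated correlation). The homeostatic microglia (adjusted p = 7.37e-05) and lysosome (adjusted p = 7.55e-05) lists lay lower and the integrated stress response list higher (adjusted p = 0.000255), each at adjusted p = 0.595 with an estimated correlation and none with a gene past the threshold. The lists of type I interferon (adjusted p = 0.000249, higher), disease-associated microglia (adjusted p = 0.000595, lower) and phagocytosis (adjusted p = 0.00259, lower) were called, each at adjusted p = 0.595 with an estimated correlation. The first was lost without WT cuprizone replicate 2 (adjusted p = 0.0894) and the others without AHR CKO cuprizone replicate 1 (adjusted p = 0.0636 and 0.0874). The lineage factor list (higher, adjusted p = 0.00412) and the homeostatic astrocyte list (lower, adjusted p = 0.00401) were called in all 12 leave-one-out fits, each at adjusted p = 0.595 with an estimated correlation. The other 6 called lists were each lost without some replicates, and with an estimated correlation ependymal stood at adjusted p = 0.639 and the rest at 0.595. Cholesterol (higher, adjusted p = 0.00452) was lost without WT control 1 or 2 or WT cuprizone 1 (largest adjusted p = 0.132). Choroid plexus (lower, adjusted p = 0.00401) was lost without WT cuprizone 1 or AHR CKO control 2 or cuprizone 2 (0.142). Cortical neuron (lower, adjusted p = 0.021) was lost without WT control 3 or cuprizone 2 or AHR CKO control 3 or cuprizone 1 (0.264). Fibroblast and meninges (lower, adjusted p = 0.0265) was lost without WT control 3 or cuprizone 1 or AHR CKO control 1 or cuprizone 2 (0.565). MHC class II (lower, adjusted p = 0.0327) was lost without WT control 3, WT cuprizone 1 or 3 or AHR CKO control 2 or cuprizone 1 (0.189). Ependymal (higher, adjusted p = 0.0468) was lost without WT control 2 or 3, WT cuprizone 2 or 3 or AHR CKO control 3 or cuprizone 1 (0.473) and after the length and GC correction (0.0924). Genes of the next smallest p were Fbxo7 (interaction 1.04), Nr1d1 (1.18), Pdia6 (-0.88) and Calr (-0.85), all at adjusted p = 0.0673, none past the threshold.

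**Figure D4:**
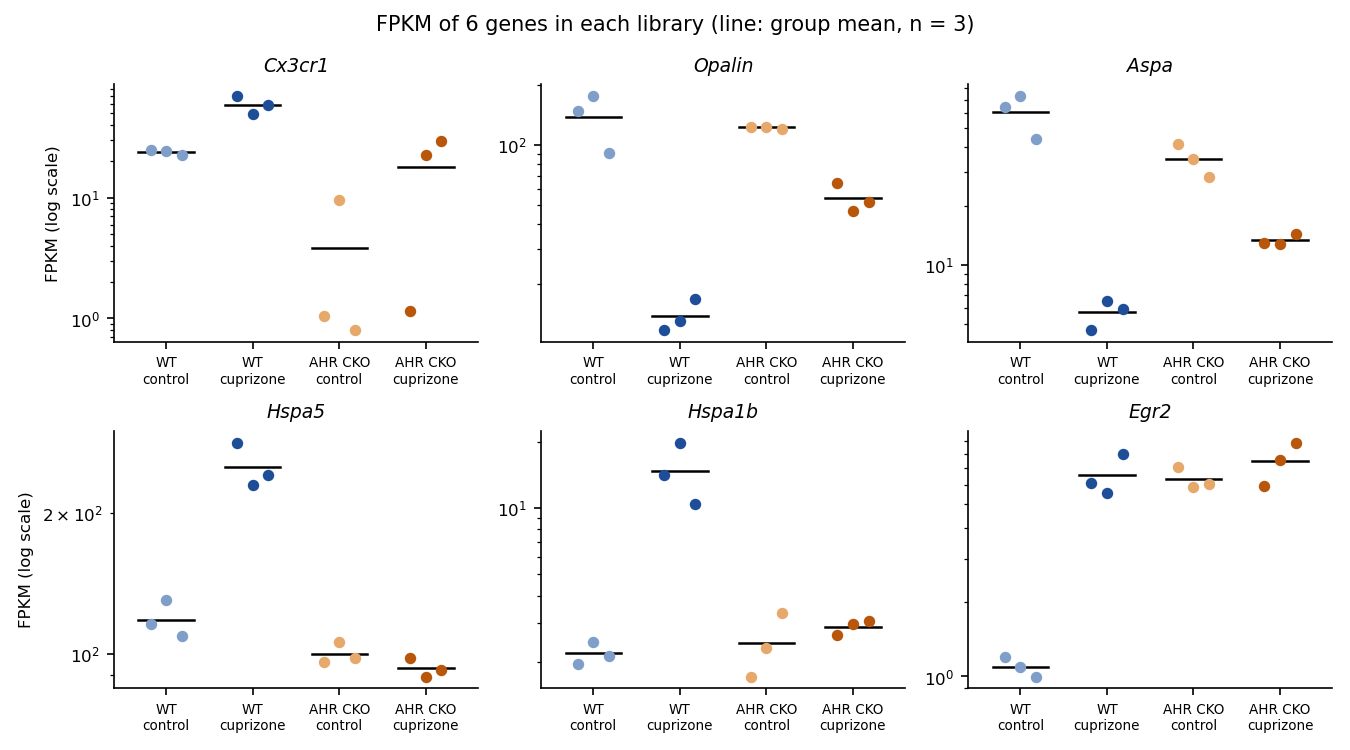
FPKM on a log scale of 6 genes in each of the 12 libraries, with 1 point per library and the group mean (n = 3) as a line. The 3 WT cuprizone libraries lie below all others for Opalin and Aspa and above all others for Hspa5 and Hspa1b, and Cx3cr1 spreads from 0.801 to 29.6 in AHR CKO.

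The interaction count of 5 (limma, with 1316 genes at an unadjusted p under 0.05) depended on single libraries. The count was 0 without WT control replicate 1, without any 1 AHR CKO control replicate or without AHR CKO cuprizone replicate 1 or 2, and 1 without WT control replicate 2, WT cuprizone replicate 1 or AHR CKO cuprizone replicate 3. It was 103 without WT control replicate 3 and 38 without WT cuprizone replicate 2, and all 5 genes passed in both of these.

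Averaged over both treatments, a set of genes differed between genotypes with 6 libraries on each side. Cx3cr1 was lower in AHR CKO at 10.8 ± 12.5 against 41.5 ± 20.3 FPKM (mean ± SD, n = 6, log2 change -2.62, adjusted p = 0.00782). Sall1, a transcription factor of microglia, stood at 8.68 ± 1.42 against 13.3 ± 1.73 (log2 change -0.56, adjusted p = 0.00305), Mertk at 8.89 ± 2.03 against 14.5 ± 3.34 (adjusted p = 0.00326) and Gpr34 at 12.9 ± 3.88 against 20.6 ± 10.5 (adjusted p = 0.00963). Of 17 homeostatic microglia genes 0 were higher, 11 lower and 6 did not pass the test (1 higher and 11 lower adjusted over the list alone). The homeostatic microglia list gave adjusted p = 0.00341, and adjusted p = 0.835 with an estimated correlation. Junb was higher at 116 ± 18.99 against 50.6 ± 23.7 (log2 change 1.29, adjusted p = 0.00032) and Egr4 at 50.9 ± 5.23 against 19.5 ± 7.36 (log2 change 1.41, adjusted p = 0.000748). Of 14 immediate early genes 10 were higher, 0 lower and 4 did not pass the test (11 higher and 0 lower adjusted over the list alone). The immediate early list gave adjusted p = 6.35e-06, and adjusted p = 0.718 with an estimated correlation. Of 32 interferon genes 12 were higher, 0 lower and 20 did not pass the test (13 higher and 0 lower adjusted over the list alone). The interferon list gave adjusted p = 4.62e-05, and adjusted p = 0.835 with an estimated correlation. Irf7 stood at 13.9 ± 11.4 against 5.75 ± 4.98 (adjusted p = 0.00453).

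Of 23 integrated stress response genes 10 were higher, 0 lower and 13 did not pass the test (14 higher and 1 lower adjusted over the list alone). The stress response list gave adjusted p = 0.00209, and adjusted p = 0.718 with an estimated correlation. Of 14 genes of MHC class I and antigen processing 6 were higher, 0 lower and 8 did not pass the test (6 higher and 0 lower adjusted over the list alone). The class I list gave adjusted p = 0.00209, and adjusted p = 0.835 with an estimated correlation. Of 34 phagocytosis genes 1 was higher, 8 lower and 25 did not pass the test (1 higher and 8 lower adjusted over the list alone). The phagocytosis list gave adjusted p = 0.0217, and adjusted p = 0.835 with an estimated correlation, and the call was lost without WT cuprizone replicate 1 or AHR CKO cuprizone replicate 1 (largest adjusted p = 0.0668). Of 33 lysosome genes 1 was higher, 9 lower and 23 did not pass the test (0 higher and 9 lower adjusted over the list alone). The lysosome list gave adjusted p = 0.032, and adjusted p = 0.903 with an estimated correlation. It was lost without WT control replicate 2, WT cuprizone replicate 1, AHR CKO control replicate 1 or AHR CKO cuprizone replicate 1 (largest adjusted p = 0.146). The reactive astrocyte list had 3 higher genes (adjusted p = 0.0339, and adjusted p = 0.835 with an estimated correlation), lost without WT control replicate 3, WT cuprizone replicate 2, AHR CKO control replicate 1 or AHR CKO cuprizone replicate 3 (largest adjusted p = 0.219). Arnt, the partner of AHR on DNA, was lower at 10.3 ± 1.96 against 13.9 ± 1.82 FPKM (log2 change -0.40, adjusted p = 0.0285). This call was lost in 6 leave-one-out fits, without WT control replicate 1 or 2, WT cuprizone replicate 2, AHR CKO control replicate 2 or AHR CKO cuprizone replicate 1 or 2 (largest adjusted p = 0.0702), and after the length and GC correction.

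Markers of other tissue moved with the genotype here as well. All 3 red blood cell genes were lower (adjusted p = 0.00209, and adjusted p = 0.609 with an estimated correlation), Hba-a2 at 0.126 ± 0.224 against 22.3 ± 11.1 FPKM (log2 change -4.18, adjusted p = 0.000311). Of 11 fibroblast and meningeal genes 10 were higher, 0 lower and 1 did not pass the test (11 higher and 0 lower adjusted over the list alone). The fibroblast list gave adjusted p = 6.35e-06, and adjusted p = 0.718 with an estimated correlation. Col1a1 stood at 2.62 ± 0.441 against 1.21 ± 0.261 (log2 change 0.71, adjusted p = 0.00159). Of 12 choroid plexus genes 3 were higher, 0 lower and 9 did not pass the test (5 higher and 0 lower adjusted over the list alone). The choroid plexus list gave adjusted p = 0.0033, and adjusted p = 0.835 with an estimated correlation. Ttr was higher at 2201 ± 1345 against 699.6 ± 1143 (log2 change 3.07, adjusted p = 0.0177). The striatal list had 1 higher gene (adjusted p = 0.0339, and adjusted p = 0.903 with an estimated correlation), a call that leaving out any of 8 libraries ended, which were replicates 1 and 2 of every group (largest adjusted p = 0.152). In all, 4630 genes differed, 2000 higher and 2630 lower by limma, of which 78 differed at least 2-fold. Higher genes were 43.2% of the calls, against 24.2% after rescaling to a common total. The count was 1910 after the length and GC correction, and log2 change and transcript length correlated across genes with Spearman rho -0.58.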

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

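The tests of transcript length, haemoglobin and Cx3cr1 given here were chosen after the results were seen, while the counts over other splits of the libraries were planned. The cuprizone effect differed between genotypes by the interaction test in 5 genes. The difference (AHR CKO minus WT, log2 scale) was -1.18 for Hspa5, -1.64 for Egr2, 1.86 for Aspa, -2.08 for Hspa1b and 2.01 for Opalin, with adjusted p between 0.0277 and 0.0465. With 1 library left out in turn, each of the 5 lost its call at least once, with the largest adjusted p at 0.123 for Hspa5 and Egr2, 0.152 for Aspa and Hspa1b and 0.182 for Opalin.

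The genotype comparisons followed transcript length: the slope of log2 FPKM on a doubling of length averaged 0.131 in WT control, 0.0517 in WT cuprizone, -0.0243 in AHR CKO control and -0.158 in AHR CKO cuprizone. After each library's trend was removed, 857 of the 2747 calls in cuprizone and 53 of the 851 in control passed in the same direction. This argues against length and GC as the whole cause for those of them with a transcript length. Genes without one were left uncorrected, so their passing says nothing on length. Their number in these parts was not counted. For the other 798 calls in control the median size fell from 0.53 (median SE 0.12) to 0.35 (0.11), with 64.9% left, and for the other 1890 in cuprizone from 0.47 (0.12) to 0.22 (0.10), with 48.2% left, so the calls ended on smaller changes at a like error. Both cannot be told apart from a length trend, since genes picked for passing only before correction can keep part of a change by chance. A batch shared by the AHR CKO libraries stays open too. WT cuprizone replicate 2, the 1 WT library with genes listed at 0, had a slope of 0.029, but 1 library decides nothing. The genotype stays open, untested.

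Haemoglobin transcripts were lower in AHR CKO. Reads shared between the near-identical copies were argued against, since the sum of the 4 haemoglobin genes was 1.25 to 54.0 FPKM in AHR CKO libraries and 125.4 to 503 in WT, so the largest AHR CKO sum was 0.431 of the smallest WT sum. Length was argued against, since other transcripts of up to 1000 nt had a median log2 change of 0.304 in the opposite direction. Less blood in the AHR CKO tissue may account for it, as all 5 genes examined (4 haemoglobin genes and Alas2) lay below WT in all 6 AHR CKO libraries, but blood left in the tissue and the genotype cannot be told apart in these samples, because every AHR CKO library is low.

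Cx3cr1 was lower in AHR CKO averaged over treatments (log2 change -2.62, adjusted p = 0.00782), with a log2 change of -2.88 in control tissue that did not pass (adjusted p = 0.0634). Fewer microglia as the whole cause were argued against by the other 16 homeostatic microglia genes, whose median log2 change was -0.187 (median absolute deviation 0.176) in control tissue and -0.531 (0.252) in cuprizone tissue, where Cx3cr1 changed by -2.36. An exchange of libraries between genotypes was not decided: 0 WT libraries lay below an AHR CKO library of the same treatment, but an exchange of all of them would leave none either. A Cre allele placed in Cx3cr1, in 1 or 2 copies, could give such values and stays open, as the AHR CKO libraries stood at 0.0439, 0.401 and 0.0334 of the WT mean in control and at 0.0196, 0.384 and 0.5 in cuprizone tissue, but no source used here names the Cre line and no value decides it. A lower level of Cx3cr1 in microglia that lack AHR stays open, untested.

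Other splits of the libraries were counted, 10 for 3 against 3, too few for a share under 0.05. The real split gave the most calls each time (1 of 10): 2324 against at most 14 for cuprizone in WT, 1403 against at most 1 in AHR CKO, 2747 against 0 between genotypes in cuprizone and 851 against 0 in control (limma). For lists, as many calls as in the real split came from 2 of 10 splits for cuprizone in WT (22, highest other 22), 6 in AHR CKO (17, highest other 24), 6 between genotypes in cuprizone (14, highest other 19) and 9 in control (6, highest other 20). Among 100 splits of genotype within treatment, 1 reached the averaged count of 4630 (highest other 28), which argues against chance between libraries, not animals. Its 12 list calls, reached by 54 (highest other 22), leave chance open. For the interaction 6 of 100 gave at least 5 genes and 15 at least 16 lists (highest other 21). This decides nothing, since the other splits carry the genotype effect into the contrast or the spread within groups, so chance stays open. The split that exchanges the genotypes in cuprizone tissue alone turns the interaction into the averaged genotype effect and gave 4630 genes.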

How the results depend on the processing

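All alternatives but the length and GC correction were planned. Of single-gene values under an alternative, 2062 kept their side of the threshold, 153 lost the call and 18 gained it, with only the lowest and highest leave-one-out fit counted. Of the list values 527 kept their call and 169 lost it, 87 of them with an estimated correlation, under which 0 lists were called in each of the 6 comparisons (camera, against 22, 17, 14, 6, 16 and 12 with the preset one, in the order cuprizone in WT, cuprizone in AHR CKO, genotype in cuprizone, genotype in control, interaction, averaged). Fry called 21, 18, 5, 3, 0 and 6 lists. In the same order, sample quality weights, which ranged from 0.338 to 6.93 over the libraries, called 5100, 4846, 8036, 4477, 2556 and 7866 genes, and a 2-fold minimum 682, 461, 166, 55, 5 and 78, by construction no more. A mean FPKM of at least 5 left 901 calls for cuprizone in AHR CKO and 673 genes shared by the cuprizone responses. Fitting only the groups compared called 1070 and 127 genes for genotype in cuprizone and in control, with fewer samples in the fit. With the length and GC correction these were 1066 and 60, the interaction 8 and the average 1910. The interaction called 1 gene with no filter and 2 with no trend in the prior variance. The cause of these shifts was not tested except where the construction shows it. Leaving out 1 library in turn gave 1594 to 2439 genes for cuprizone in WT, 840 to 1553 in AHR CKO, 777 to 3305 for genotype in cuprizone, 4 to 1428 in control, 0 to 103 for the interaction and 3397 to 4965 averaged, 726 to 1035 genes shared by the cuprizone responses, and 19 to 24, 15 to 21, 10 to 16, 6 to 12, 12 to 19 and 9 to 13 lists.

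With the replicate number as a block (replicate block), 1945, 1047, 1806, 51, 0 and 3790 genes were called (limma, the interaction against 5 genes without the block, where 1316 had an unadjusted p under 0.05). Of the list calls it ended 2, antioxidant between genotypes in cuprizone tissue (adjusted p = 0.0547) and ependymal for the interaction (0.0549). The numbers do not pair the samples: of 18 same-numbered pairs, 3 had deviations from their group means that correlated over 0.1 (range -0.34 to 0.25), and 3 of the 12 libraries matched best a library of their own number.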

Other observations

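The test of border tissue given here was chosen after the result was seen. Single clock genes passed, while the clock list was not called. In WT, cuprizone lowered Nr1d1, a repressor of the clock, from 65.7 ± 8.72 to 31.96 ± 5.899 FPKM (mean ± SD, n = 3, log2 change -1.02, adjusted p = 0.000159) and Dbp, a clock output gene, from 77.5 ± 12.8 to 37.7 ± 9.58 (log2 change -1.04, adjusted p = 0.0031). In AHR CKO, Nr1d1 was 64.2 ± 5.25 and 71.4 ± 5.497 and Dbp 85.2 ± 3.98 and 122 ± 28.1, and the difference between genotypes did not pass (adjusted p = 0.0673 and 0.122). Within cuprizone tissue, Ciart was 3.62-fold higher in AHR CKO at 20.8 ± 3.64 against 5.74 ± 1.65 (log2 change 1.71, adjusted p = 0.000868). Of the 15 clock genes, 2 rose, 4 fell and 9 did not pass the test with cuprizone in WT, and 15 compared between genotypes in cuprizone tissue gave 4 higher and 3 lower (adjusted p = 0.133 and adjusted p = 0.773). The hour of tissue collection is not given in the sources.

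With the length and GC correction, chosen after seeing the data, the interaction passed for Nr1d1 (adjusted p = 0.0422), the disulfide isomerase Pdia6 (0.0422) and Calr, calreticulin (0.0284).

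A hypothesis is that the higher fibroblast and meningeal genes of AHR CKO libraries could come from more choroid plexus and bordering tissue in the dissected samples. The scores of the 2 lists, which share no genes, were related within each genotype, since both lists were higher in AHR CKO and a value over all libraries would hold that difference. Within WT Pearson r was 0.966 and Spearman rho 0.829 (n = 6, exact permutation p = 0.00833 and 0.0583, adjusted p = 0.0125 for r over 3 relations computed), with r 0.618 without the 2 libraries farthest from the median, but both lists were also called higher with cuprizone in WT. Within AHR CKO they were 0.82 and 0.771 (n = 6, exact permutation p = 0.0625 and 0.103, adjusted p = 0.0625 for r), and r was -0.188 without the 2 farthest there, so it rests on them. The relation passed in WT by r alone and not in AHR CKO, so the hypothesis stays open, and a change of fibroblasts was not tested apart from it.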
